A study of Taeniopygia guttata with 46 samples.

How the data were processed

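RNA from Area X, a song nucleus in the striatum of the zebra finch, was measured on one-colour custom Agilent oligonucleotide arrays. The labels describe adult males older than 120 days that were kept alone overnight on a 12 h light cycle. Birds were taken in the morning before they sang, or directly after they had sung for 0.5 h or for whole hours from 1 h to 7 h. Per the labels, RNA was isolated with Picopure, 1.5 to 2 ng of it was amplified with WT-Ovation Pico, and 2.2 ug of cDNA was labelled with Cy3. The 46 arrays were grouped by hours of singing as their titles state: 6 arrays of silent birds, 5 each at 0.5, 1, 2, 3, 4 and 7 h, 6 at 5 h and 4 at 6 h. The titles of the silent arrays also name 1 h, which the labels do not explain; they were taken as arrays of birds that had not sung. The labels describe 9 groups of 6 birds, 54 in all; 46 arrays were analysed here. The description of silent replicate 6 speaks of singing, while its title and source say silent, and it was kept as silent.

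The authors scanned the arrays on a GenePix scanner and made one Feature Extraction text file per array, with version 9.5.1.1 for 24 arrays and 9.5.3.1 for 22. The deposited processed signal is an intensity in scanner counts, and per the file headers it was background-subtracted by a spatial fit and detrended multiplicatively, with substituted values for spots near background. The deposited series matrix holds log2 values whose array medians lie between 8.24 and 8.48; they carry no background subtraction, and how the authors normalised them between arrays is not stated. The series matrix was used as an alternative and the processed signal for the values reported.

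The arrays hold 43084 distinct 60-base probes besides the controls, on 43552 spots. Spots with an outlier mark of the scanner software (0.016% of spots) were dropped, the spots of a probe were averaged on the log2 scale, and the 75th percentile of each array was subtracted. A level of 0 is therefore the 75th percentile of an array. A probe was tested when the software called it well above background on at least 4 arrays; 38370 probes passed, 34 of them that lost a value to an outlier mark were left out, and 38336 were tested. On single arrays, 16867 to 41244 probes (39.1% to 95.7%) were well above background, and 13169 probes were so on all 46. The depth of an array is its signal over background; the number of arrays limits the precision of every value. No genome was used.

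Linear models were fitted with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8, and statmod 1.5.0), with moderated variances that follow the mean level. One fit over 46 arrays gave the 8 comparisons of a singing time with silence and an F test over them. A second fit over the 40 singing arrays, with the slide set as a covariate, gave an F test among the 8 singing times and a linear slope per hour of singing. P values were adjusted by Benjamini and Hochberg within each test, two-sided, at 0.05. Groups of at least 5 named genes were tested with camera at a preset correlation of 0.01 and again with an estimated one. All these choices were fixed before the data were examined.

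Most probes carry only a clone identifier, which the reference used here does not pair with a gene, so they are reported as clones. Gene names were read from the 319 probes named on the array itself: 149 of them carry a gene name (136 names), and 96 probes of 84 names were tested. A gene is represented by the brightest of its probes over all arrays. None of the 24 gene lists written in advance had 5 tested named members, so 12 groups of the genes named on the array were written instead, after the probe names were seen and before any value was. Among the genes that were to be named in any case, FOS, ARC, NR4A1, JUN, ATF3, BDNF, FOXP2, HSPA8, UCHL1, SYT4 and PENK have no named probe and were not analysed here. EGR1 was always to be named; the other genes named by rule are the 12 with the largest rise and the 12 with the largest fall at any singing time, among those past the F test over the 8 comparisons with all arrays of that time on the same side of the silent mean; the 10 steepest slopes in each direction among named genes past the trend test; and members with the smallest adjusted p of each group tested. ESR1, SCAMP1, GPM6A, the histone genes, the dopamine receptors and the clones were chosen after their values were seen. Where a gene was not well above background on any silent array, its change is also given as a lower bound: each silent value was raised to the lowest value that any probe well above background had on that array, and the ratio of the singing mean to the silent mean is written as at least that fold.

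The procedure was tested on simulated data with the means and spreads of these probes and 200 changed probes. Over the comparisons with silence and the F tests tried, 12% to 22% of log2 changes of 1 were recovered. Of log2 changes of 2, 63% to 73% were. The simulated noise was independent between arrays and held no slide or scan structure, so the test says nothing about such batches. Alternatives to the background method, scaling, filter, weighting, blocks and arrays used were tried, and every array was left out in turn; the closing section gives their effect. Other splits of the arrays into groups of the same sizes were refitted 100 times for each count.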

Results

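Gene expression in Area X, the striatal nucleus of the circuit with which songbirds learn and produce song, was measured in adult male zebra finches before and after hours of singing. There were 46 arrays in 9 groups: 6 of silent birds, 5 each after 0.5, 1, 2, 3, 4 and 7 h of singing, 6 after 5 h and 4 after 6 h. Singing birds had produced more than 25 bouts per 0.5 h. Hours of singing ran together with the time of day, since by the labels silent birds were taken in the morning (their titles also name 1 h, unexplained) and no silent group of a later hour was analysed here. Between 16867 and 41244 of 43084 probes were well above background on an array, and the 75th percentile of the signal ranged from 175.7 to 1466.9 counts. Levels are log2 signals relative to that percentile of the same array. Arrays of silent birds shared no slide, slide set or scan day with arrays of singing birds, so for every comparison with silence the slide batch and the state of the birds cannot be told apart. The 40 singing arrays lay on 2 slide sets, each with arrays of all 8 singing times. Within each set the scan days ran with hours of singing. In the first, arrays up to 3 h were scanned before those from 4 h on. In the second, arrays at 0.5 h and 1 h were scanned first and those at 7 h last. Of the silent arrays 5 of 6 were of the newer array printing, while all 5 at 0.5 h and all 5 at 1 h were of the older.

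The first question was how EGR1 (known as ZENK in songbirds), a transcription factor induced within minutes by neuronal activity, followed singing in Area X. EGR1 rose steeply by 0.5 h of singing and was highest then. It was still higher than in silent birds at 1 h. At 7 h its mean over both slide sets was close to the silent mean. The level of EGR1 was 2.02 ± 0.87 (SD, n = 6) in silent birds and 4.49 ± 0.56 (SD, n = 5) at 0.5 h. The log2 change of EGR1 at 0.5 h was 2.47 (SE 0.41, limma adjusted p = 2.54e-05), with 5 of 5 arrays above the silent mean. At 1 h EGR1 was higher by 1.3 on the log2 scale (SE 0.41, adjusted p = 0.0295). Between 2 h and 6 h the change of this probe, the brightest of EGR1, ranged from 0.27 to 1.05 and was not past the threshold at any of these times (adjusted p from 0.08 to 0.676). At 7 h the change was 0.06 (adjusted p = 0.945); it was -0.48 with arrays of the first slide set alone and 0.87 with those of the second (adjusted p = 0.462 and 0.319). All 12 probes of EGR1 were highest at 0.5 h, with log2 changes from 2.24 to 3.46, each past the threshold. The numbers of these 12 probes past the threshold were 7 at 1 h, 3 at 2 h, 10 at 3 h, 10 at 4 h, 1 at 5 h, 4 at 6 h and 0 at 7 h (limma, with 2 of 12 under an unadjusted p of 0.05).

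The decline of EGR1 was also tested among singing birds alone, where slide sets can be compared. EGR1 differed among the 8 singing times (F test, adjusted p = 0.0123) and fell by 0.263 per hour (SE 0.052, adjusted p = 0.00264). Its slope was -0.361 per hour in the first slide set (adjusted p = 0.000419) and -0.118 in the second (adjusted p = 0.472), and the time course differed between the sets (interaction, adjusted p = 0.0196). In the first set the mean of EGR1 went from 4.12 at 0.5 h to 1.55 at 7 h. In the second it was 5.05 at 0.5 h (2 arrays of the same slide) and 2.59 at 1 h. From 2 h to 7 h the means of the second set lay between 2.42 and 3.44, with 2.9 at 7 h, so it showed no fall after 1 h. The rise at 0.5 h was 2.1 with arrays of the first set alone (adjusted p = 0.00131) and 3.03 with those of the second (adjusted p = 5.01e-05). With the slide as a random block, the slope was -0.249 (adjusted p = 0.111), and within slides it was -0.231 (95% CI from -0.576 to 0.115). With the scan day as a block it was -0.206 (95% CI from -0.458 to 0.046, adjusted p = 0.434). On the newer array printing alone, which has 0 arrays at 0.5 h and 1 h, it was 0.041 (adjusted p = 0.911). The change at 1 h was past the threshold in 12 of 17 alternatives. Among them, it was 0.56 with the second slide set alone (adjusted p = 0.469). That set has 2 arrays at 1 h, with EGR1 at 2.155 and 3.018. The lower is singing 1 h replicate 4, the array lowest in D1A, described below. Without that array, a choice made after the values were seen, the change at 1 h over both sets was 1.59 (limma adjusted p = 0.0104). The slope was then -0.284 per hour.

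**Figure D1:**
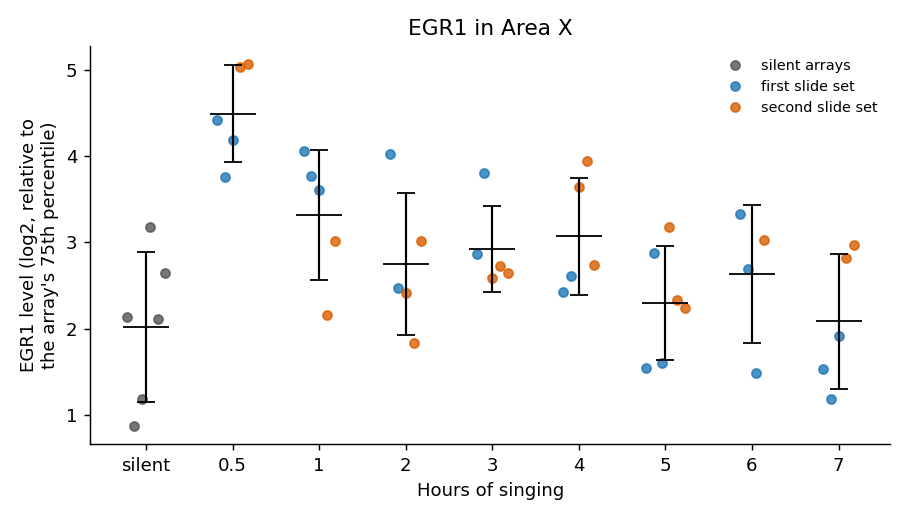
Level of EGR1 (log2 signal relative to the 75th percentile of the array, y axis) by hours of singing (x axis, silent birds first); points are arrays and bars are means with SD. The mean is 2.02 in silent birds and 4.49 at 0.5 h.

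The second question was which other genes named on the array changed between silent and singing birds. JPH4, which couples the plasma membrane to the endoplasmic reticulum in neurons, was among the risers. The probes named for the complement regulator CD59A and the interferon-induced OASL rose as well. Names are as given on the array, and whether a probe measures the zebra finch gene of that name was not tested. Most of these genes were close to background in silent birds, so the sizes of their changes are poorly fixed. Of 84 named genes tested, 17 changed over the 8 comparisons (F test), and all 17 of them rose. JPH4 at 6 h went from -2.87 ± 0.84 (SD, n = 6) to 1.38 ± 0.82 (SD, n = 4), a log2 change of 4.25 (SE 0.71, adjusted p = 2.62e-05), with 4 of 4 arrays above the silent mean. CD59A at 3 h went from -5 ± 0.91 (SD, n = 6) to -1.48 ± 0.64 (SD, n = 5), a change of 3.53 (SE 0.51, adjusted p = 4.29e-06), with 5 of 5 arrays above the silent mean. OASL at 6 h went from -3.63 ± 0.94 to -0.34 ± 0.73 (adjusted p = 6.58e-05), with 4 of 4 arrays above the silent mean. GGN, a gene of germ cells, rose by 3.59 at 6 h. JPH4, GGN, CD59A and OASL were well above background on 4, 1, 1 and 3 of 6 silent arrays.

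The other 8 of the 12 largest risers were not well above background on any silent array, and their rises are lower bounds. For AARD, ZCCHC5, ABCA6 (a lipid transporter of the ABC family) and ZSWIM2, the naming rule picked 2 h. There they were at least 4.41-fold, 4.46-fold, 2.15-fold and 2.03-fold higher than in silent birds. None of the 12 largest risers differed among singing times (F test, adjusted p from 0.398 to 0.969), so no time of a peak is shown. SEMA4F, a semaphorin, was at least 1.82-fold higher at 2 h. BATF2, a leucine zipper transcription factor, and NPTN, a synaptic adhesion protein, were at least 3.1-fold and 2.1-fold higher at 6 h. The probe named for the olfactory receptor Olfr1388 was at least 3.33-fold higher at 0.5 h. At these times ZSWIM2 and SEMA4F were well above background on 2 of 5 singing arrays, NPTN on 2 of 4 and Olfr1388 on 3 of 5. AARD, ZCCHC5 and ABCA6 were so on 4 of 5 and BATF2 on 3 of 4. Singing values were not raised, so the bounds also rest on singing values not well above background. In limma the adjusted p of these 8 genes at the times picked ranged from 9.75e-07 for Olfr1388 to 0.000514 for NPTN. The times were picked for a large change, with every array above the silent mean. Over the alternatives the lowest log2 changes of these genes were between 0.38 (NPTN) and 1.02 (AARD), so the bounds hold for the reported processing only. BATF2 and NPTN lost their calls in the series matrix (adjusted p = 0.0564 and 0.0571), NPTN also in the second slide set, which has 1 array at 6 h (log2 change 2.86, adjusted p = 0.0578). AARD, ZCCHC5, ABCA6, ZSWIM2 and SEMA4F lost theirs on the newer printing, which has 1 array at 2 h. LARP5, an RNA-binding protein, was past the threshold at all 8 times, with log2 changes from 0.9 to 1.66. BLMH, FOXP4 and SLC13A3 were the remaining genes past the F test.

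Calls among named genes were also counted by brightness, without a test of the difference. Of 9 named genes with a mean level of 0 or more, EGR1 and FNDC9 rose at any time and SCAMP1 fell, and 1 of 9 (EGR1) passed the F test. Of 75 dimmer genes, 42 rose at any time, 5 fell and 16 passed the F test. Among the bright genes, the sodium pump subunit ATP1B1 and the neuronal RNA-binding protein ELAVL4 had adjusted p of 0.54 and 0.817 in the F test. Over all probes, the median log2 change was 0.56 in the dimmest of 5 brightness classes and 0.04 in the brightest. Probes with at least 50% GC rose by a median of 1.03, against 0.06 for the others. Among the largest risers, JPH4, GGN, OASL and BATF2 are represented by probes of 55% GC, so they belong to the class that rose as a whole. The probes of the remaining largest risers have 38.3% to 45% GC.

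Few named genes fell, and since all 17 past the F test rose, the following were chosen after their values were seen. ESR1, the estrogen receptor alpha, fell by 1.29 at 0.5 h (SE 0.34, adjusted p = 0.00574), with 5 of 5 arrays below the silent mean, and by 1.18 at 5 h (adjusted p = 0.00878). Its F test gave an adjusted p of 0.0502. SCAMP1, a membrane protein of secretory vesicles, fell by 0.74 at 5 h (SE 0.19, adjusted p = 0.00427), with 6 of 6 arrays below the silent mean, and was past the threshold at 5 times. GPM6A, a neuronal membrane glycoprotein, fell by 1.7 at 5 h (SE 0.5, adjusted p = 0.014), with its call lost in the first slide set alone (-1, adjusted p = 0.177). SCAMP1 at 5 h lost its call there as well (-0.55, adjusted p = 0.109) and in the series matrix (-0.51, adjusted p = 0.0566); over all its alternatives the adjusted p of SCAMP1 ranged from 0.000204 to 0.109, and that of GPM6A from 0.000456 to 0.177. The histone genes Hist1h4h and Hist2h2be fell by 1.86 and 1.67 at 6 h (adjusted p = 0.0345 and 0.0336), whereas Hist2h3c1 changed by 0.53 (adjusted p = 0.361). Hist2h2be was well above background on 2 of 6 silent arrays. With normexp background the histone genes did not fall as a group: their median change ranged from -0.31 to 0.26 over the 8 times, with 3 calls up and 1 down. In the second slide set alone the log2 change of ESR1 at 0.5 h was -1.07 and not past the threshold (adjusted p = 0.0781). With normexp background it was -0.28 (adjusted p = 0.364, the highest of 16 alternatives, whose lowest was 0.0012).

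Groups of named genes were compared to ask which functions moved. Whether a group was called depended on how the correlation between its genes was treated. With a preset correlation, olfactory receptor genes, ion transport genes, genes of metabolism and growth and a mixed group of other named genes were called as higher at some times, and with an estimated correlation none of them was. Transcription factors, synaptic genes, dopamine receptors and axon guidance genes were not called as groups at any time, although JPH4 and BATF2 rose among them. In camera with a preset correlation, 16 of 72 tests were called, all of them upward: other named genes at 8 times, olfactory receptors at 6 times, ion channels and transporters at 0.5 h (adjusted p = 0.0468) and metabolism at 2 h (adjusted p = 0.018). With a correlation estimated from the data, 0 of the 72 tests were called by camera; the lowest adjusted p was 0.347, and 0 had an unadjusted p under 0.05. Of the 7 olfactory receptors, 4 were past the threshold at 0.5 h and 5 at 2 h. All 7 were at background on every silent array, and of the 4 past it at 0.5 h only Olfr1388 has a lower bound above 1-fold. Olfr461, Olfr131 and Olfr284 were well above background on 1 of 5 singing arrays each. Of 6 ion transport genes, 1 (SLC4A3) was past the threshold at 0.5 h; it was well above background on 0 of 6 silent and 1 of 5 singing arrays, and no bound can be given. Of 10 metabolism genes, 5 were past the threshold at 2 h, with BLMH at least 1.59-fold and EDA2R at least 1.3-fold higher. The medians of the groups called were above 0 at 8 of 8 times under each of the 5 scalings tried. Of 4 immune genes, too few for camera, OASL, CD59A and CD53 (at least 1.18-fold) rose at 0.5 h.

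Dopamine receptors, through which dopamine acts in Area X, were chosen for description after their values were seen. D1A was higher in all 6 arrays at 5 h than the mean of silent birds, but the change was not past the threshold. In limma 0 of 40 tests (5 receptors at 8 times) were past the threshold, and 3 had an unadjusted p under 0.05. D1A went from 2.73 ± 0.34 (SD, n = 6) to 3.9 ± 0.4 (SD, n = 6) at 5 h, a log2 change of 1.17 (SE 0.44, adjusted p = 0.0576). A single array weighed on this test: singing 1 h replicate 4 had a D1A level of -1.07, while the other 45 arrays lay between 2.21 and 4.4. Without it, a choice made after the values were seen, D1A was past the threshold at 5 of 8 times, with a change at 5 h of 1.17 (SE 0.25, adjusted p = 0.000769). That array was also lowest or highest by more than 1 on the log2 scale for 174 of the bright probes, against a median of 3 for the others.

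**Figure D2:**
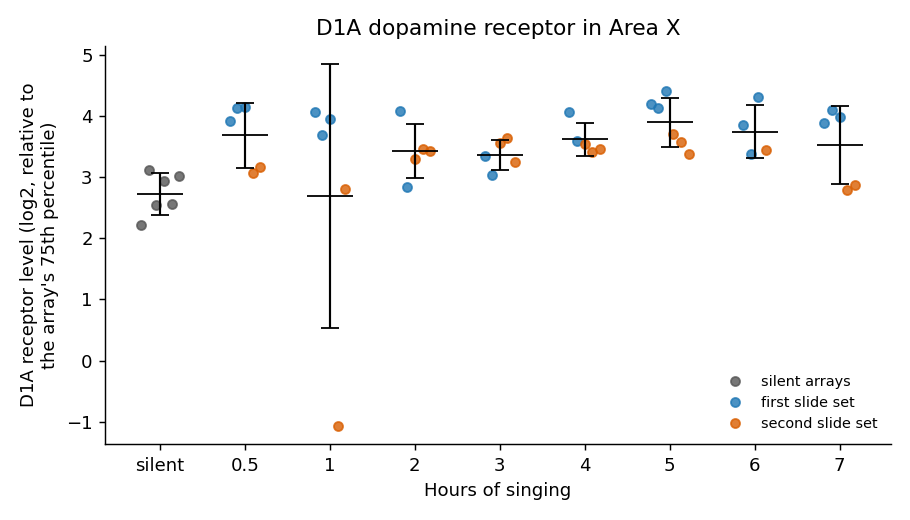
Level of the dopamine receptor D1A (log2 signal relative to the 75th percentile of the array, y axis) by hours of singing (x axis); points are arrays and bars are means with SD. Singing 1 h replicate 4 lies at -1.07, and silent birds have a mean of 2.73.

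Over all probes, the comparison with silence asked how much of the transcriptome of Area X differed after each time of singing. Many probes differed at each time, and most of them were higher in singing birds. CD59A was past the threshold at all 8 times and JPH4 at 7 of them. The counts at 0.5, 3, 4 and 7 h depended on single arrays. Of 38336 probes, limma called 7410 at 0.5 h, 4561 at 1 h, 7550 at 2 h, 7253 at 3 h, 5166 at 4 h, 6377 at 5 h, 8286 at 6 h and 2810 at 7 h. Leaving out 1 array lowered the count to 4355 at 0.5 h (without replicate 3), 3732 at 3 h (without replicate 2) and 3350 at 4 h (without replicate 5). Without 1 array the count at 7 h ranged from 626 (without replicate 2) to 4739 (without replicate 4), and it was 258 with only both groups in the fit. Between 75.9% and 85% of them were higher in singing birds. The F test over the 8 comparisons called 5093 probes. The median change of all probes was 0.09 to 0.13 with this scaling and -0.01 to 0.01 in the series matrix, where 45.7% to 73.4% of the called probes were higher. With the slide as a random block the counts ranged from 2215 at 7 h to 7005 at 0.5 h. With arrays of the first slide set alone the counts were 7257 at 0.5 h and 8175 at 7 h, and with the second alone 4395 and 781.

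**Figure D3:**
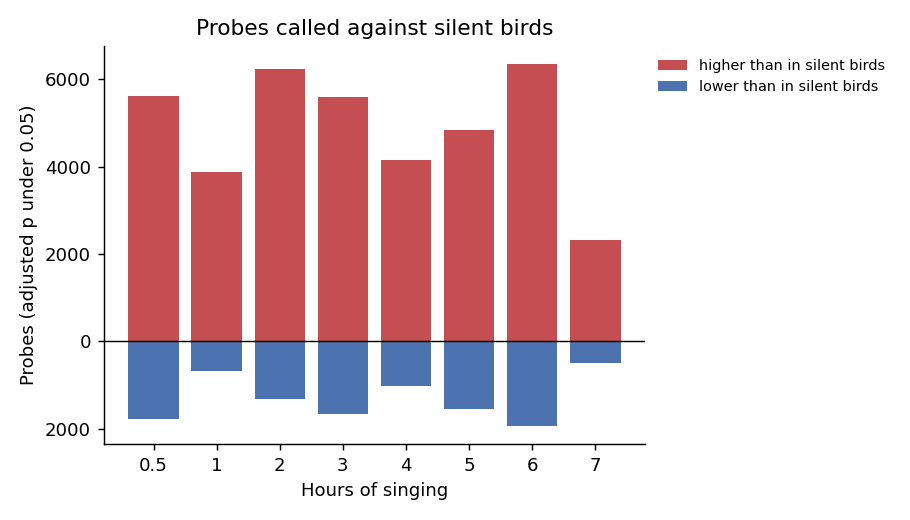
Number of probes past an adjusted p of 0.05 against silent birds (y axis) by hours of singing (x axis), with bars for probes higher and lower in singing birds. At 6 h 6347 probes were higher and 1939 lower; at 7 h 2311 were higher and 499 lower.

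The first principal component of all tested probes held 29.2% of the variance and set silent arrays apart. Silent arrays lay between -171.3 and -108.2, and 38 of the 40 singing arrays between -44.5 and 177. The remaining singing arrays were a pair at 7 h, scanned last of the singing arrays, and lay at -134.7 and -89.5. This pair was scanned after silent replicates 1 to 3 and before silent replicates 5 and 6. The other 3 arrays at 7 h lay between 19.9 and 85. EGR1 on that pair was 2.82 to 2.97, against 1.18 to 1.92 on the other 3. D1A on that pair was 2.78 to 2.87, against 3.88 to 4.09. Without the pair, 6545 probes differed at 7 h and EGR1 had a log2 change of -0.48.

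**Figure D4:**
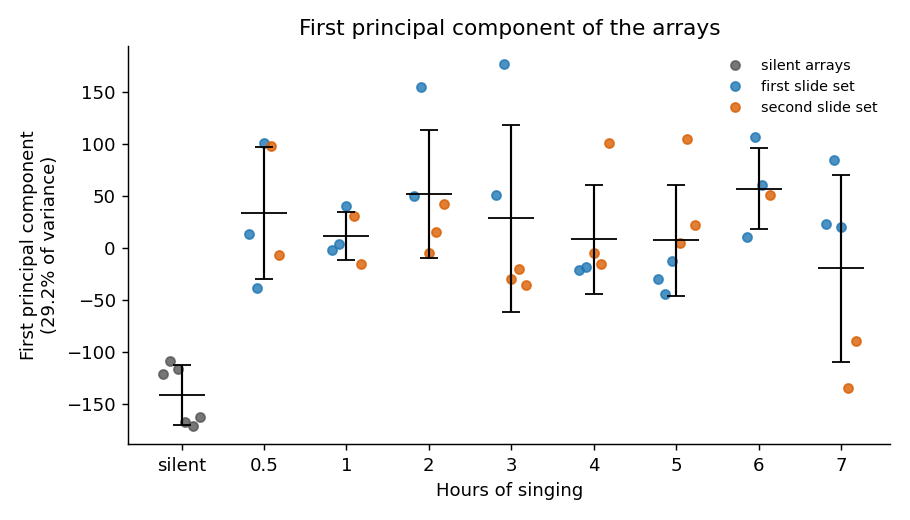
Score of each array on the first principal component (y axis, 29.2% of the variance) by hours of singing (x axis); points are arrays. Silent arrays lie at or below -108.2, and a pair of 7 h arrays, scanned last of the singing arrays, lies at -134.7 and -89.5.

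Comparisons among singing times asked which transcripts changed as singing went on. Fewer probes were called among singing times than between silence and singing. The counts are not like measures, since the comparison with silence also holds the slide batch of the silent arrays. The test among singing times averages over slide sets, between which the time course of 7024 probes differed. EGR1 was the 1 named gene past the F test and the 1 past the trend. Of the comparisons with 0.5 h, the one at 7 h called the most probes and the one at 1 h the fewest. The F test among the 8 times called 224 probes; 51 of them were highest at 0.5 h and 38 at 7 h, while 72 were lowest at 0.5 h and 40 at 7 h. Against 0.5 h, 3 probes differed at 1 h, 16 at 2 h, 41 at 3 h, 65 at 4 h, 173 at 5 h, 28 at 6 h and 219 at 7 h. With the slide as a random block, 20 probes passed the F test.

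A linear trend over hours of singing was found for 705 probes, of which 471 rose and 234 fell. Clone 0057P0001G06 rose with hours of singing and clone 0058P0058C06 fell, in both slide sets. The clones are not paired with a gene name here, and they were chosen after their values were seen. Clone 0057P0001G06 had a slope of 0.43 per hour (SE 0.039, adjusted p = 3.37e-10), 0.458 in the first slide set and 0.389 in the second (adjusted p = 3.73e-05 and 0.00328). Its mean was -3.44 ± 0.85 (SD, n = 6) in silent birds, -3.64 ± 0.59 (SD, n = 5) at 0.5 h and -0.8 ± 0.28 (SD, n = 5) at 7 h. Clone 0058P0058C06 had a slope of -0.459 per hour (SE 0.041, adjusted p = 3.37e-10), -0.52 in the first set and -0.368 in the second (adjusted p = 2.15e-07 and 0.00734). Its mean was 1.26 ± 0.33 (SD, n = 6) in silent birds and -1.87 ± 0.94 (SD, n = 5) at 7 h. Within slides the slopes of both clones were 0.406 and -0.379 and not past the threshold (adjusted p = 0.599 and 0.689). With the scan day as a block they were 0.275 and -0.244 (adjusted p = 0.0912 and 0.175), and on the newer printing alone 0.235 and -0.243 (adjusted p = 0.237 and 0.466). The slopes of both clones kept their calls but were smaller with normexp background (0.183 and -0.316) and in the series matrix (0.134 and -0.257). Fitted in each slide set alone, 64 probes were called in both, 50 of them with the same sign (30 rising and 20 falling) and 14 with opposite signs. The count of 705 depended on the fit: it was 1105 without 0.5 h replicate 1, 377 with median scaling, 76 with the slide as a random block, 1 on the newer printing alone and 0 in limma with the slide as a fixed block (2493 at unadjusted p under 0.05).

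**Figure D5:**
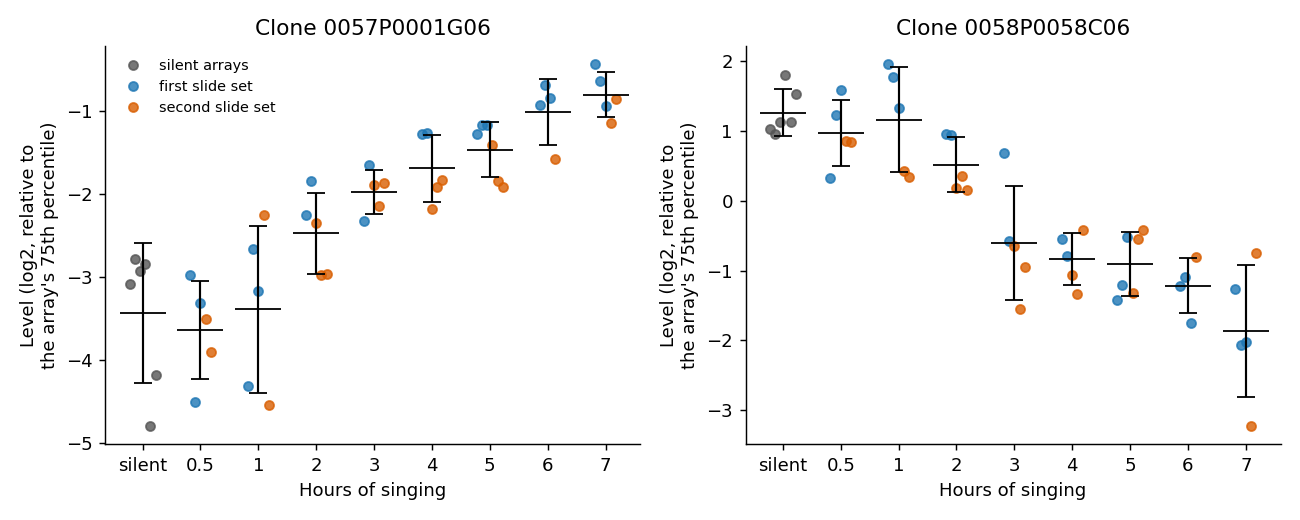
Levels of clones 0057P0001G06 and 0058P0058C06 (log2 signal relative to the 75th percentile of the array, y axis) by hours of singing (x axis); points are arrays and bars are means with SD. The means at 7 h are -0.8 and -1.87, against -3.44 and 1.26 in silent birds.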

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

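The tests of GC content, of scaling to the 75th percentile and of a slide batch for the excess of rises, of one faulty probe for EGR1, and of the slide set for probes called in both sets, with its shuffles, and the reversal of hours in the second set were chosen only after the result was seen.

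More of the called probes were higher than lower in singing birds at each of the 8 times. GC-rich probes rose by 0.97 more than the others, as was predicted if GC content played a part. With GC dependence removed, 75.1% to 82.8% of the called probes were still higher, against 75.9% to 85% in the reported fit. This argues against GC content as the whole cause, and the removal changed the share of higher calls little. A slide batch cannot be told apart from a response to singing, because silent and singing arrays share no slide. On a score of singing against silence, the 7 h pair scanned last of the singing arrays lay 79.3% of the way to silence. The way was counted from the other 7 h arrays to silent replicates 1 to 3, and the score restates the first principal component. With GC dependence removed, upward calls were at least 3.01 times as many as downward ones. Scaling stays open, since the share went down to 54.5% at its lowest with quantile normalization. Unspecific signal stays open too: 35 control probes, whose sequences are not from the zebra finch and which lie outside the comparisons, rose by a median of 0.48, but 10 of them were well above background on at least 4 arrays, and the 10 E1A probes, 9 of them so measured, rose by a median of 0.19, while 24 other controls of unstated origin, 20 of them so measured, rose by 0.57.

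EGR1 differed among the 8 singing times (adjusted p = 0.0123), and its time course differed between the slide sets (adjusted p = 0.0196). One faulty probe was excluded, since the other 11 of 12 probes were also highest at 0.5 h, and so was GC content, with a slope of -0.255 after its removal. A slide batch cannot be told apart for the slope: within slides it was -0.231, with an interval that includes 0. A fall of EGR1 after 0.5 h of singing may be biological, as a hypothesis that these slides leave open.

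In 705 probes, clones 0057P0001G06 and 0058P0058C06 among them, the level followed hours of singing. A difference between slide sets could also give many such calls: with hours reversed in the second set 1554 probes were called, more than the 705. Of the 705, 99.4% had the same sign in both sets, and with reversed hours 98.5% of the 1554 did. A call in the joint fit selects for the same sign, so this agreement decides nothing. The lists called in fits of 1 set alone are other lists. Of the probes called in the first set, 48.5% had the same sign in the second. Of those called in the second, 40.5% had the same sign in the first, and 47.8% of all probes did. The time course of 7024 probes differed between the sets. Of the 64 probes called in both sets, 78.1% (50) had the same sign. As many were given by 1 of 100 shuffles of single arrays within the sets and 3 of 100 of whole slides, the real order included. The highest other counts were 0 and 242, and 6 of 99 other whole-slide shuffles had any probe called in both sets. This argues against the slide set for the number that agree, not for single probes, since the 50 were picked by their agreement. The 14 with opposite signs go with a difference between the sets. The order of slides, which hold neighbouring hours, stays open. The scan day cannot be told apart: with it as a block 1.6% of the 705 probes kept their call and 78.9% their sign, with a median slope of 0.48 times and a median SE of 2.33 times the reported one, whereas 89.9% kept the call with GC content removed, which argues against GC content. For clones such as 0057P0001G06, a response to hours of singing or to the time of day may explain a trend seen in both sets, and the 2 were not separable here.

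Other splits of the arrays were tested for each count, 100 per count with the real one. At each of the 8 times from 0.5 h to 7 h, 1 split of 100 (the real one) gave a count as large. The real counts in order of time were 7410, 4561, 7550, 7253, 5166, 6377, 8286 and 2810. The highest of the others were 4053, 222, 3498, 4702, 2908, 465, 3534 and 2197. For any singing time 1 split of 100 gave a count as large, with 5093 probes against 2. In the comparisons with silence the splits moved single arrays between silent and singing groups, which share no slide. A slide batch alone could therefore make the real count the largest, and no conclusion about singing is drawn from these splits. For the F test among singing times 2 of 100 splits gave a count as large (224 real, 644 highest other), and for the trend 2 of 100 (705 real, 2247 highest other). These splits were drawn within slide sets; a split that calls several times the real count points to a structure of the arrays besides hours of singing. For gene groups called by camera, 7 of 100 splits gave as many (16 real, 20 highest other), so chance was not excluded.

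Single arrays lay far from the others of their group in 15 of 180 groups tested, where 9 are expected by chance. D1A was -1.07 on singing 1 h replicate 4, and 4.07 on singing 4 h replicate 1. SCAMP1 was 1.9 on singing 1 h replicate 4 and 1.51 on singing 6 h replicate 1. AARD was -2.77 and SEMA4F -4.07 on singing 6 h replicate 1. GGN was -4.43 and ZCCHC5 -3.07 on singing 1 h replicate 5. CD59A was -0.37 and EGR1 3.8 on singing 3 h replicate 2. BATF2 was -6.58 on silent replicate 4, and ZSWIM2 was -2.09 on singing 4 h replicate 5, whose score on the first principal component was 101.2. The 75th percentile of the signal was 1066.1 on singing 3 h replicate 1 and 856.4 on singing 7 h replicate 1.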

How the results depend on the processing

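The settings that remove GC dependence, use the array printing, leave out the pair of 7 h arrays scanned last or the array lowest in D1A, or fit slide or scan day as fixed blocks were chosen after seeing the data; where no reason is given, the cause was not tested.

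Of 457 alternative counts, 401 were within 1.5 times the reported one and 56 were not; of 1436 alternative values of single genes and clones, 1374 kept direction and side of the threshold, 40 lost and 11 gained a call, and 11 reversed. EGR1 at 0.5 h kept its call in all 17 alternatives (2.1 to 3.03) and without any array (2.24 to 2.7). JPH4, GGN, Olfr1388, CD59A and OASL kept their calls in all alternatives, but not their sizes: the lowest changes were 1.83, 0.93, 0.72, 0.94 and 1.38, and those of AARD, ZCCHC5, ABCA6 and ZSWIM2 1.02, 0.63, 0.47 and 0.52. AARD, ZCCHC5, ABCA6, ZSWIM2 and SEMA4F lost their calls at 2 h on the newer printing, which has 1 array at 2 h; a lone array is assumed to vary like the other groups. Reversals concerned EGR1: at 7 h its change was 0 with normexp background, -0.08 with quantile normalization, -0.02 with median scaling, -0.03 in the series matrix, and -0.48 both in the first slide set and without the pair scanned last; leaving out single arrays gave -0.17 to 0.29. It was -0.17 without silent replicate 2, -0.1 without silent replicate 3, -0.12 without 7 h replicate 4 and -0.16 without 7 h replicate 5. It was 0.87 in the second slide set and 1.1 on the newer printing. The slope of EGR1 was 0.041 on the newer printing alone, which has 0 arrays at 0.5 h and 1 h. EGR1 at 1 h lost its call with quantile normalization (1.3), median scaling (1.08), the series matrix (1.21), slide as a random block (1.25) and the second slide set (0.56), and without silent replicate 2 or 3 or 1 h replicate 1, 2 or 3 (1.07 to 1.23). D1A at 5 h was past the threshold in 9 of 18 alternatives, and without 1 h replicate 1 or 4.

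With probes well above background on all arrays, fewer were tested, and the counts from 0.5 h to 7 h were 1447, 852, 1240, 1481, 1317, 1864, 1820 and 769, with 1443 at any time. Array weights gave 9055 at 1 h, 7481 at 7 h, 10621 at any time, 533 among singing times and 1216 with a trend. The series matrix gave 1848 at 1 h, 3438 at 4 h and 549 at 7 h. The second slide set, with 1 array at 6 h, gave 4395 at 0.5 h, 4587 at 3 h, 3825 at 6 h, 781 at 7 h and 2269 among singing times; the first gave 8175 at 7 h, 11615 at any time and 584 among singing times. The printing as a block gave 2915 at 1 h and 446 with a trend; the newer printing alone gave 1024 at 2 h, 3902 at 3 h, 3446 at 6 h, 578 at 7 h, 1497 among singing times and 1 with a trend. At 7 h the count was 5911 with normexp background, 1735 with quantile normalization, 258 with only both groups compared in the fit and 6545 without the pair scanned last. Median scaling gave 80 among singing times and 377 with a trend, slide as a random block 20 and 76, and slide as a fixed block 30 and 0 (limma, 2493 at unadjusted p under 0.05). Scan day as a fixed block gave 0 among singing times (limma, 3887 at unadjusted p under 0.05) and 508 with a trend, 11 of them among the reported 705. With an estimated correlation camera called 0 gene groups (0 at unadjusted p under 0.05).

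Without single arrays, the counts were 4355 (without 0.5 h replicate 3) to 8240 at 0.5 h, 3260 to 4381 at 1 h, 5284 to 7396 at 2 h, 3732 (without 3 h replicate 2) to 7119 at 3 h, 3350 (without 4 h replicate 5) to 5054 at 4 h, 4895 to 6131 at 5 h, 5526 to 7916 at 6 h, 626 (without 7 h replicate 2) to 4739 (without 7 h replicate 4) at 7 h, 3739 to 5531 at any time, 149 (without 0.5 h replicate 5) to 272 among singing times, 494 to 1105 (without 0.5 h replicate 1) with a trend and 13 to 19 for camera. At 7 h it was also 1503 and 1758 without silent replicates 5 and 6, and 1630 and 817 without 7 h replicates 1 and 3.

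Probes called at a given time were mostly higher under the 75th percentile (75.9% to 85%) and normexp background (81.2% to 89.1%), and less so with quantile normalization (54.5% to 68.7%), median scaling (57.7% to 78.5%) and the series matrix (45.7% to 73.4%). Median scaling moved the median change of all probes to -0.19 to 0.04, quantile normalization to -0.1 to -0.02 and normexp background to 0.13 to 0.22. BATF2 and NPTN lost their calls at 6 h in the series matrix (0.42 and 0.38), and NPTN also in the second slide set (2.86) and on the newer printing (2.63). Signal over background limits genes at background on the silent arrays, such as AARD and NPTN, to lower bounds.

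Replicate numbers do not pair the samples: over 173 pairs of arrays with the same number the median correlation of residuals was -0.01, against 0 for other pairs. With the replicate number as a block the counts from 0.5 h to 7 h were 7083, 4240, 7330, 6900, 4679, 6445, 7753 and 2322, with 4673 at any time, 181 among singing times, 641 with a trend and 15 for camera.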

Other observations

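No test in this part was planned; the array lowest in D1A and the probes that overlap EGR1 were examined after their values were seen. On singing 1 h replicate 4, D2 was -5.52 (45 other arrays from -4.06 to -0.1) and the long form of D2 was -4.26 (others from -3.67 to -1.1). D1B was -3.98, and 1 array was lower, at -4. Of the bright probes, 148 were lower and 26 higher on this array than on all other 45 by more than 1 on the log2 scale; the next array, singing 3 h replicate 1, had 45. Without it the counts at 0.5 h and 1 h were 7540 and 4248. No explanation was tested.

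Clone 0206P0015N07 and 3 other probes that share at least 25 bases with probes of EGR1 rose by 2.57 to 3.27 at 0.5 h.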
